A study of Homo sapiens with 4 samples.

How the data were processed

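RNA sequencing was read from 4 libraries of A549, an established human lung cancer cell line. The cells carried a stable lentiviral short hairpin RNA (shRNA), either a negative control or one against LIMA1, and were left untreated or given nutlin-3a at 10 µM, a small molecule that blocks the binding of MDM2 to p53. RNA was taken 24 h later, per the labels' protocols. Groups were taken from the sample titles, which write si where the protocols and the design text write shRNA; the protocols' word is used here. The header of the fourth library names EPLIN, another name of LIMA1.

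The genome build hg19 and the tools bcl2fastq 1.8.3, Bowtie2 2.0.12 and Cuffnorm 2.2.1 are named, per the submitters' processing notes, with no role or order; the gene annotation is not given in the sources used here. The deposited values are a signal per gene that was found, from the values themselves, to be fragment counts divided by 1 size factor per library, not divided by gene length. In each library most low values were whole multiples of 1 step, which is what 1 fragment is worth (0.943, 0.990, 0.993 and 1.07 in untreated control, untreated LIMA1 shRNA, nutlin-3a control and nutlin-3a LIMA1 shRNA cells). Between 0.5 and 1000 fragments, 85.5% to 86.3% of a library's values lay within 0.1 of a whole number. This is under the 95% set for treating the values as whole reads, so no count test was run. The other values were taken here as estimates for genes that share reads with an overlapping or near-identical gene model, which no label or header states. Of the 12742 genes measured, 9716 had values in the range that could be checked, and 1791 (18.4%) had at least 1 value that was not whole; they are called shared-read genes here. Genes that could not be checked stayed in when shared-read genes were left out.

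The analysis had been planned, before the data were examined, for FPKM. Its settings were carried over to normalized counts by taking 1 FPKM as 32 fragments, from a transcript of 2 kb and a library of 16 M fragments. A gene was measured when its mean over the 4 libraries was at least 30 normalized counts, which kept 12742 of the 42113 gene models in the files, 635 of them long noncoding gene models whose names start with lnc-. Differences were taken between log2(normalized count + 1) values, with the pseudocount of 1 as planned; a fold change on this scale understates the change of low genes. A gene was called higher or lower at a difference of at least 1 or at most -1. The design has 1 library per group, so there are no replicates, no test was made and no p-value is given. An additive model of line and treatment, which would take the response difference as its error, was not run. Every difference compares libraries, not conditions.

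There were 5 contrasts: nutlin-3a against untreated in each cell line, LIMA1 shRNA against control shRNA in each treatment, and the response in LIMA1 shRNA cells minus that in control shRNA cells. Genes were also sorted by the mean of both nutlin-3a responses, which does not favour a smaller response in either line. For 22 gene lists fixed before the data were examined, and the union of the 5 p53 target lists, the median over measured members is given with its 95% order-statistic interval (the range, for the histone list of 5 measured genes). It was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A median stands apart when its percentile is below 2.5 or above 97.5; this describes these libraries and is not a test. The genes named are LIMA1, MDM2 and CDKN1A, the 8 highest and 8 lowest of each contrast (and of the means of the 2 nutlin-3a and the 2 LIMA1 shRNA contrasts) with a mean of at least 150 normalized counts and no small RNA, and up to 4 members of each list per contrast with the largest differences. Some genes that this rule names are not reported here. Intervals of a ratio of 2 libraries are exact Clopper-Pearson 95% intervals of the fragment counts; they and the floor of 3 fragments per library cover counting error only, since reads carry no molecular identifiers.

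Libraries held 15.2 to 16.7 M fragments, so the precision is close in all 4. The calling step was tested on simulated Poisson counts for nutlin-3a in control shRNA cells, over 12386 genes: all 47 genes changed 4-fold and 22 of 50 changed 2-fold were called, as were 3 of 12192 unchanged genes. These counts hold counting error alone, so they give no rate of false calls for real cultures or shared reads. Alternatives tried were other pseudocounts, library scalings, filters and sizes, and, chosen after seeing the data, a mean of at least 1, a pseudocount of 30, genes without shared reads, genes without lnc- models, and removal of the trend with transcript length and GC content. The reference used for lengths was GENCODE 29, on another build than the files, so no coordinates are given; 11484 of the 12742 genes (90.1%) had a length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, with matplotlib 3.10.9 for the plots.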

Results

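The transcriptomes of 4 A549 cell populations were compared in a design of 2 cell lines by 2 treatments, with 1 library per group. Control shRNA cells gave 16.7 M fragments untreated and 15.8 M with nutlin-3a; LIMA1 shRNA cells gave 16.5 M untreated and 15.2 M with nutlin-3a. LIMA1 encodes EPLIN, a LIM-domain protein that binds and bundles actin filaments. Nutlin-3a stabilises p53 by displacing it from its ubiquitin ligase MDM2, and the stated question was how loss of LIMA1 changes the genes that p53 switches on. Values are normalized fragment counts as deposited, and differences are on the log2(normalized count + 1) scale. As there were no replicates, differences are given as sizes.

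LIMA1 itself was low in both libraries labelled LIMA1 shRNA. In untreated cells it stood at 416 normalized counts with control shRNA and 68.3 with LIMA1 shRNA, a difference of -2.59 (counting interval -2.99 to -2.24). With nutlin-3a the values were 866 and 133, a difference of -2.69 (-2.99 to -2.43). LIMA1 was also higher with nutlin-3a than without, by 1.06 in control shRNA cells (0.89 to 1.23) and 0.95 in LIMA1 shRNA cells (0.52 to 1.41).

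**Figure D1:**
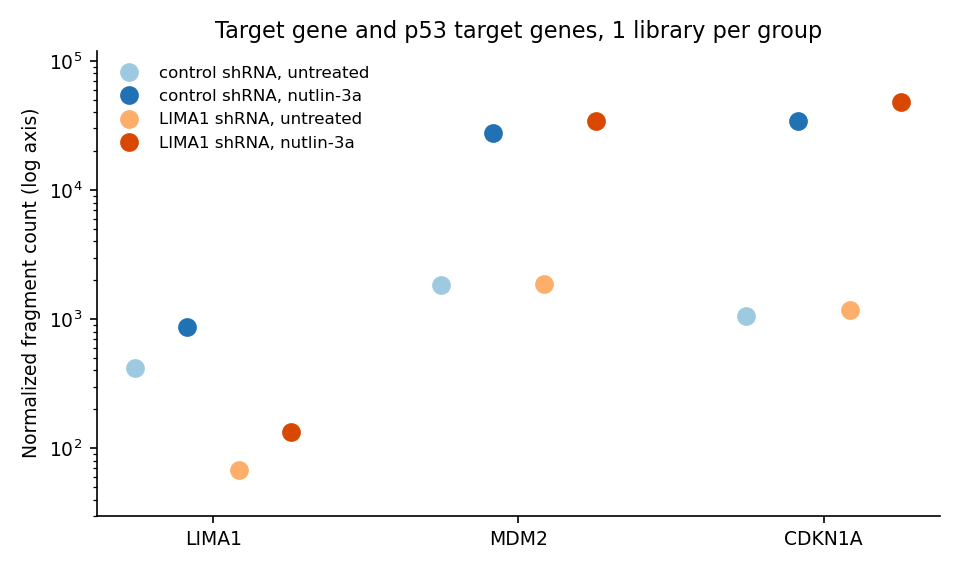
Normalized fragment counts (log axis) of LIMA1, MDM2 and CDKN1A in each of the 4 libraries, 1 point per library. LIMA1 lies at 68.3 and 133 in the LIMA1 shRNA libraries against 416 and 866 in the control libraries, while MDM2 and CDKN1A lie at 27580 or more in both nutlin-3a libraries.

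In control shRNA cells, nutlin-3a went with much higher levels of p53 target genes and much lower levels of cell division genes. CDKN1A, which encodes the cell-cycle inhibitor p21, stood at 34078 normalized counts with nutlin-3a and 1066 without, 31.9-fold higher (30.1 to 33.9). MDM2, the p53 ligase and itself a p53 target, was 14.9-fold higher (14.3 to 15.7), at 27580 against 1844. Of 12742 genes, 706 were higher by at least 1 and 719 were lower by at least 1. The largest difference was at CLCA2, a chloride channel regulator, which had 0 fragments untreated and 500 normalized counts with nutlin-3a, at least 177-fold higher against a floor of 3 fragments per library. SLC52A1, a riboflavin transporter, was higher by 6.03, WDR63 by 5.36, the semaphorin receptor PLXNB3 by 5.31, the lipid phosphatase INPP5D by 4.98 and CYGB, which encodes cytoglobin and had shared reads, by 4.91.

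Of the 100 measured genes in the 5 p53 target lists, 66 were higher and 3 lower, with a median of 1.46 (interval 1.25 to 1.76) that none of the 10000 random lists reached. Among the lower genes were FANCC at -1.44 and WRAP53 at -1.73. In the cell-cycle arrest list 10 of 13 genes were higher, among them the antiproliferative gene BTG2 (3.77), the sestrins SESN1 (3.35) and SESN2 (2.99) and GADD45A (2.83). Of 22 apoptosis and death receptor genes 15 were higher, including SPATA18 (4.22), TP53I3 (3.81), the death receptor FAS (3.71), TP53INP1 (3.49) and the BH3-only gene BBC3 (2.36). The DNA repair list had 5 of 12 genes higher, such as POLH (2.37), the nucleotide-supply gene RRM2B (2.10), DDB2 (1.91) and XPC (1.78). The feedback list had 6 of 11 higher, led by TRIM22 (4.78) and MDM2 (3.90). In the metabolism, autophagy and secretion list 30 of 42 were higher, with ABCA12 at 4.66, the lipoxygenase ALOX5 at 4.04, GLS2 at 4.02 and the mitochondrial reductase FDXR at 3.91.

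Cell division genes were lower almost as a block. All 48 measured G2/M and mitotic genes had negative differences and 47 were lower by at least 1, with a median of -4.62 (-4.81 to -4.12). The kinesin KIF2C was at -5.48, the histone variant gene CENPA at -5.44, the mitotic kinase PLK1 at -5.34 and the phosphatase CDC25C, which had shared reads, at -5.07. Of 48 S-phase and replication genes 46 were lower, with a median of -3.38 (-3.93 to -2.95); RRM2, a subunit of ribonucleotide reductase, went from 4727 to 102 normalized counts and the replication factor MCM10 from 1092 to 22.8. The lowest differences outside shared-read genes were at CKAP2L (-5.98), the kinase NEK2 (-5.70) and FAM111B (-5.70).

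Other lists differed less. Hypoxia and glycolysis genes had a median of -0.37 (percentile 0.06), with CA9 at -2.11 and HK2 at -1.43. NRF2 targets had a median of 0.21 (percentile 99.2), with the aldehyde dehydrogenase ALDH3A1 at 121294 against 22883 normalized counts. YAP/TAZ targets (median 0.26) and ribosomal protein genes (0.16) also stood apart on the high side. Sterol, epithelial, mesenchymal, interferon-stimulated and secreted-factor lists had medians of 0.10, 0.13, -0.21, 0.21 and -0.13 and did not stand apart; nor did the actin, ATF4, histone, lung lineage and housekeeping lists, at -0.07, -0.04, 0.28, 0.17 and -0.15. Within them TAP1 (1.62, with shared reads) was higher, and OAS3 (-1.78) and CXCL8 (-1.34) lower. The balance of higher and lower genes depended on the setting: means of at least 150 left 364 higher and 518 lower, whereas upper-quartile scaling gave 788 and 662. SLC52A1, WDR63 and CYGB had only 9.43, 5.66 and 11.3 normalized counts in untreated cells.

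In LIMA1 shRNA cells p53 target genes were again higher, and cell division genes lower, with nutlin-3a. CDKN1A was at 48106 normalized counts against 1178, 40.8-fold higher (38.6 to 43.3), and MDM2 at 33982 against 1857, 18.3-fold higher (17.5 to 19.2). In all, 929 genes were higher and 775 lower. CLCA2 again had 0 fragments untreated and 535 normalized counts with nutlin-3a, at least 180.2-fold higher. SLC52A1 was higher by 6.63, the hemidesmosome collagen COL17A1 by 5.87, INPP5D by 5.37 and WDR63 by 5.30.

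Of the 100 p53 target genes 67 were higher and 3 lower, with a median of 1.54 (1.32 to 1.82), again above every random list. The arrest list had 9 of 13 genes higher, the apoptosis list 16 of 22, the repair list 5 of 12, the feedback list 6 of 11 and the metabolism list 31 of 42. BTG2 was higher by 4.34, TP53I3 by 4.25, FAS by 3.96 and SESN1 by 3.79, while SESN2, at 0.84, was under the size for a call. Of the G2/M genes 47 of 48 were lower (median -4.82, -5.03 to -4.29), and of the S-phase genes 46 of 48 (median -3.26, -3.67 to -2.58). MCM10 was at -6.79, FAM111B at -6.72, the E2F family repressor E2F8 at -6.62 and CLSPN at -6.41.

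In this line the list of ATF4 and unfolded protein response genes was also lower with nutlin-3a. Its median was -0.52 (-1.16 to -0.13), below every random list, and 13 of 34 genes were lower and 0 higher. CHAC1, a glutathione-degrading enzyme gene, was at -2.80, the secreted glycoprotein gene STC2 at -2.65, the folate enzyme MTHFD2 at -1.85 and asparagine synthetase, ASNS, at -1.61. Hypoxia genes had a median of -0.32 (percentile 0.58), interferon-stimulated genes 0.37 (99.5), YAP/TAZ targets 0.29 (99.2; 0.17 without the length and GC trend) and ribosomal protein genes 0.13 (99.2; 0.21 after upper-quartile scaling). NRF2, sterol, actin, epithelial, mesenchymal, secreted-factor, histone, lineage and housekeeping medians were 0.07, -0.0088, -0.07, 0.12, 0.02, 0.02, 0.20, 0.0026 and -0.15 and did not stand apart. Restricting the counts to means of at least 150 left 482 genes higher and 573 lower. Lower genes then outnumbered higher ones, as they did with a log2 size of 2 (246 and 302).

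The 2 responses, which share no library, were alike across genes. Of the genes called higher, 599 were called in both lines, against 51.5 for independent lists, and of those called lower 583, against 43.7; with means of at least 150 the higher genes in both were 333. Further, 4 genes were higher in control and lower in LIMA1 shRNA cells and 6 the reverse. Across the 12742 genes Pearson's r was 0.88 and Spearman's rho 0.87, which describe these genes and do not treat them as replicates.

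**Figure D2:**
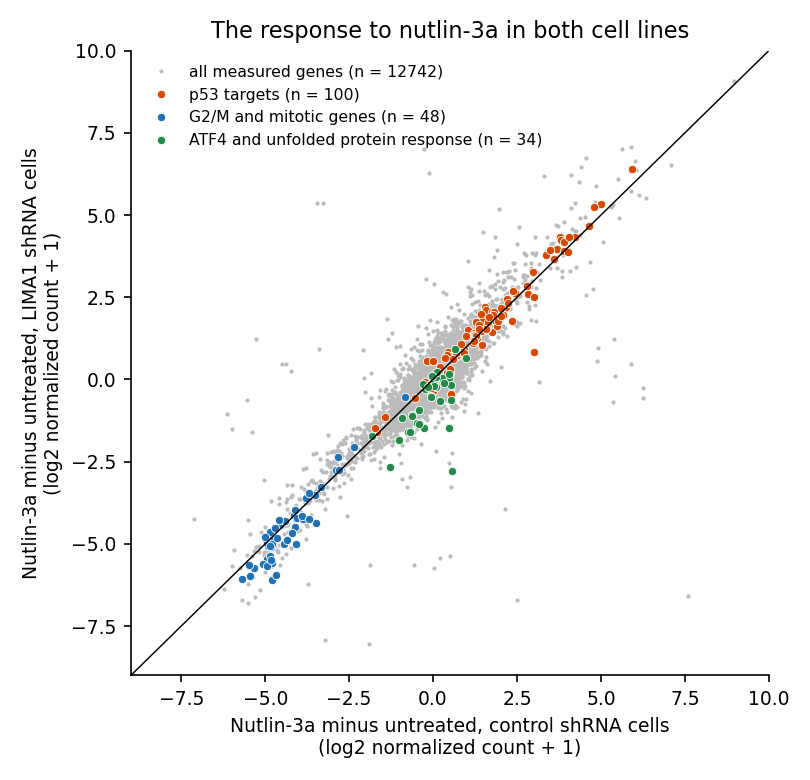
Nutlin-3a minus untreated difference (log2 normalized count + 1) of each of 12742 genes in control shRNA cells (x axis) and LIMA1 shRNA cells (y axis), with 3 gene lists coloured and a line of equal response. The p53 targets (medians 1.46 and 1.54) and the G2/M genes (-4.62 and -4.82) lie near the line, and ATF4 genes such as CHAC1 (0.57 and -2.80) lie below it.

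Between the cell lines, far fewer genes differed. In untreated cells 132 genes were higher and 261 lower with LIMA1 shRNA. Members of the ATF4 and unfolded protein response list were among the higher genes. CHAC1 was at 602 normalized counts against 37.7, 15.6-fold higher (11.6 to 22.6). DDIT3, which encodes the stress transcription factor CHOP, was at 680 against 124, 5.43-fold higher (4.53 to 6.63). STC2 was at 2950 against 432 and SESN2 at 756 against 129. The TNF family ligand gene CD70 was higher by 2.92 and TNFSF9, which encodes the 4-1BB ligand, by 2.17; the splicing regulator PTBP2 was higher by 1.88. On the low side were CHGB, a secretory granule protein gene, at 242 against 1524 normalized counts, the sialyltransferase ST6GAL2 (-2.49), the heat shock family gene HSPA2 (-2.14), the sulfotransferase SULT2B1 (-1.95) and the kinase PSKH1 (-1.86).

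The ATF4 and unfolded protein list had a median of 0.49 (0.17 to 0.89), which none of the 10000 random lists reached. In it 7 of 34 genes were higher, among them TRIB3 (1.41), ASNS (1.37) and the serine synthesis enzyme PHGDH (1.18), and 1, the cystathionine enzyme gene CTH, was lower (-1.39). In all 27 members lay above 0, MTHFD2 at 0.81 and SARS at 0.43 among them. Mesenchymal genes had a median of 0.22 (percentile 99.9), with the matrix genes TNC at 2.75 and FN1 at 0.82, but SNAI1 (-1.83), CDH11 (-1.55) and FSTL1 (-1.06) were lower. Sterol biosynthesis genes had a median of 0.17 (0.12 to 0.36; percentile 99.7), with 25 of 27 above 0 and HMGCS1 at 0.83; it was 0.11 after upper-quartile scaling and 0.28 without the length and GC trend. The median of NRF2 targets was 0.17 (percentile 99.6), with SLC7A11 at 0.66.

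The p53 target list did not stand apart in untreated cells, with a median of 0.05 (percentile 67.3) that was -0.00056 after upper-quartile scaling. Only 3 of its 100 members reached a difference of 1, SESN2 (2.54), PMAIP1 (1.49) and ALOX5 (1.03). Its arrest, apoptosis, repair, feedback and metabolism parts had medians of 0.06, 0.04, 0.05, 0.04 and 0.06, those of apoptosis, repair and feedback being negative after upper-quartile and equal-total scaling. Ribosomal protein genes had a median of -0.10, G2/M genes of -0.04 and the 5 histone genes of -0.55, all standing apart on the low side. Without the length and GC trend these medians were -0.055, -0.0077 and -0.32. Across genes, differences were related to transcript length (Spearman's rho 0.15 untreated and 0.18 with nutlin-3a) and to GC content (-0.17 and -0.094). S-phase genes were at 0.11 (percentile 98.4), and at 0.056 after upper-quartile scaling. Actin and focal adhesion genes, the group nearest to the known role of LIMA1, had a median of 0.05 (-0.05 to 0.17; percentile 37.1; -0.0088 after upper-quartile scaling), and 0 of 42 reached a difference of 1; the filamin gene FLNA was at 0.47 and the myosin gene MYH9 at 0.56. Epithelial genes had a median of 0.0049, with EPCAM (-1.47) and CLDN2 (-1.14) lower. YAP/TAZ, interferon-stimulated, secreted-factor, hypoxia and lineage lists had medians of 0.12, 0.06, -0.00088, 0.07 and 0.20. Housekeeping genes were at 0.03, and at -0.02 and -0.01 after upper-quartile and equal-total scaling. Among secreted factors IL11 (-1.84), CCL2 (-1.77) and IGFBP7 (-1.31) were lower. Low genes carried many of the calls: with a pseudocount of 30, 57 genes were higher and 98 lower, and with means of at least 150, 42 and 68.

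**Figure D3:**
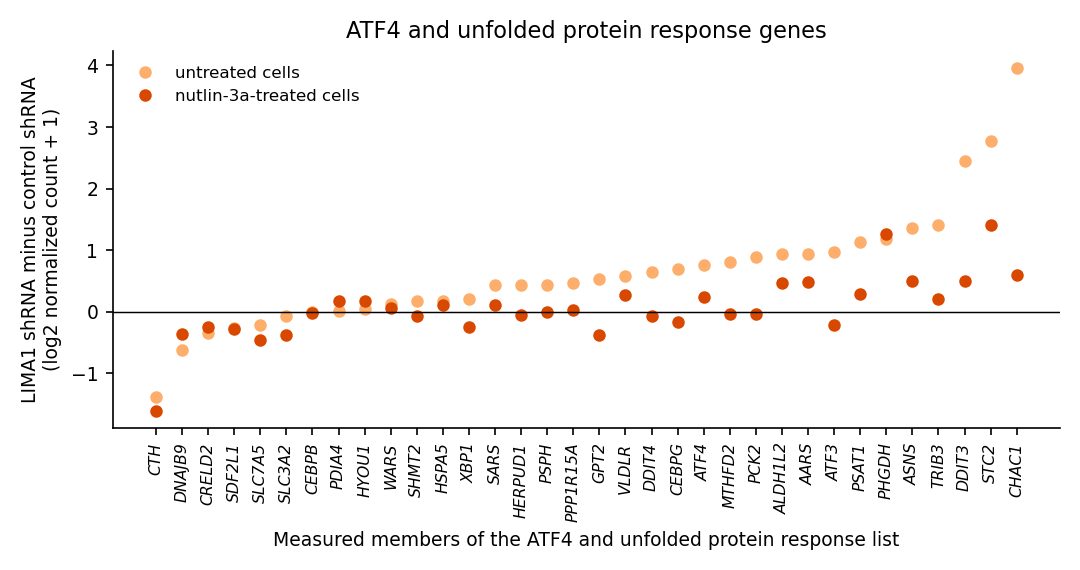
LIMA1 shRNA minus control shRNA difference (log2 normalized count + 1) of the 34 measured ATF4 and unfolded protein response genes, in untreated (light) and nutlin-3a-treated (dark) cells, 1 point per gene and treatment. In untreated cells 27 genes lie above 0, with CHAC1 at 3.96, and the median is 0.49; with nutlin-3a the median is 0.01 and CHAC1 is at 0.59.

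With nutlin-3a, 161 genes were higher and 247 lower in LIMA1 shRNA than in control shRNA cells. CD70 (2.39), TNFSF9 (1.98), PTBP2 (1.64), the formin DAAM2 (1.77, with shared reads) and the noncoding model lnc-IGFL3-2 (1.70) were higher, and CHGB (-2.69) and SULT2B1 (-2.45) lower. Of the ATF4 list 2 of 34 genes were higher, STC2 (1.41) and PHGDH (1.27), and CTH was lower (-1.61); its median was 0.01 (-0.07 to 0.21; percentile 22.0). CHAC1 was at 0.59 and DDIT3 at 0.49. The p53 targets had a median of 0.21 (0.13 to 0.25), which none of the random lists reached, with 79 of 100 members above 0; only ALOX5 (1.32) reached a difference of 1. The parts were at 0.27 for arrest, 0.22 for apoptosis, 0.10 for repair, 0.18 for feedback and 0.18 for metabolism; repair (percentile 81.2) and feedback (97.1) did not stand apart.

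Mesenchymal genes had a median of 0.37 (-0.01 to 0.58), above every random list, with TNC at 2.72, ZEB2 at 1.47 and FN1 at 1.16, and SNAI1 at -1.73. G2/M genes, already low with nutlin-3a, had a median of -0.29 (-0.41 to -0.17), below every random list, with AURKB (-1.22), KIF4A (-1.14), CENPM (-1.04) and UBE2C (-1.02) lower. S-phase genes had a median of 0.23 (0.05 to 0.39), above every random list, with E2F2 (-1.22), RRM2 (-1.17) and MCM10 (-1.02) lower. With a pseudocount of 30 the mesenchymal, G2/M and S-phase medians were 0.24, -0.18 and 0.14. Sterol genes (0.20), hypoxia genes (0.17), ribosomal protein genes (-0.12) and the 5 histone genes (-0.54) stood apart; the ribosomal median was -0.057 without the length and GC trend, and the histone median 0 without a filter on low values. Actin, epithelial, YAP/TAZ, interferon-stimulated, secreted-factor, NRF2, lineage and housekeeping medians were 0.09, 0.08, 0.03, 0.13, 0.08, 0.05, 0.12 and -0.01 and did not. The mucin MUC5B was at 62248 against 29917 normalized counts and CTGF at 79.3 against 266. With a pseudocount of 30, 82 genes were higher and 99 lower, with means of at least 150, 59 and 78, and without shared-read genes 106 were higher. Without a filter on low values the direction turned, with 2448 genes higher and 1688 lower. There the directions are not counted alike. In LIMA1 shRNA cells with nutlin-3a 1 fragment is worth 1.07, so against 0 it reaches a difference of 1. In the other libraries it is worth 0.993 or less and does not.

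**Figure D4:**
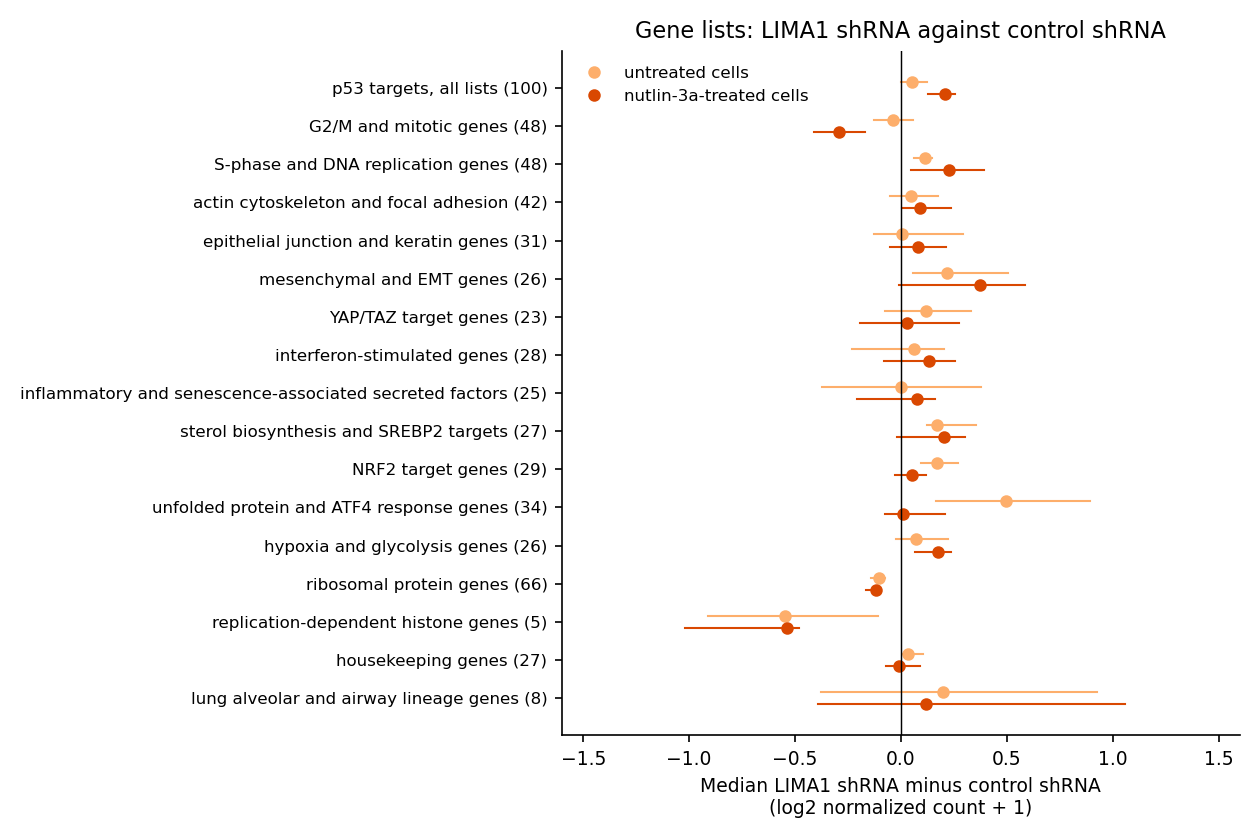
Median LIMA1 shRNA minus control shRNA difference (log2 normalized count + 1) of 17 gene lists, with the number of measured genes in brackets, in untreated (light) and nutlin-3a-treated (dark) cells. Points are medians and bars their 95% order-statistic intervals over genes (the range for the 5 histone genes); the ATF4 list is at 0.49 and 0.01 and the p53 targets at 0.05 and 0.21.

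The 2 LIMA1 shRNA differences, which also share no library, overlapped in 57 higher and 122 lower genes. Independent lists would give 1.67 and 5.06. With means of at least 150 the overlaps were 22 and 35, and with a pseudocount of 30, 26 and 54. Both differences compare the same cell lines, so a lasting difference between the lines would show in both. It cannot be told apart from an effect of the LIMA1 shRNA. Across genes Pearson's r was 0.49 and Spearman's rho 0.58. By the mean of both differences, CD70, CHAC1, STC2, TNFSF9, PTBP2, AHCYL2 and lnc-IGFL3-2 were among the 8 highest, and CHGB, LIMA1, ST6GAL2, SULT2B1 and PSKH1 among the 8 lowest. CHAC1 reached a difference of 1 in untreated cells only. AHCYL2 was at 3139 against 923 normalized counts untreated and 3921 against 1261 with nutlin-3a.

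Most genes that were higher with nutlin-3a had a larger, not a smaller, response in LIMA1 shRNA cells. Of the 788 genes with a mean response of at least 1, 209 had a smaller response in LIMA1 shRNA cells (26.5%, exact 95% interval 23.5% to 29.8%) and 579 a larger one. Intervals of such shares treat genes as independent and cover no variation between cultures. The median response of the 788 genes was 1.57 in LIMA1 shRNA and 1.37 in control shRNA cells, and the median difference was 0.22. The same genes had a median LIMA1 shRNA minus control difference of -0.092 in untreated cells and 0.12 with nutlin-3a. For the p53 target lists the median difference was 0.08 (0.02 to 0.16), above every random list, with 67 of 100 members above 0. The random lists were matched on expression and not on the response to nutlin-3a. The 788 genes had a larger median, 0.22, so these values do not set p53 targets apart from other induced genes. CDKN1A differed by 0.35, MDM2 by 0.29, BTG2 by 0.57, TP53I3 by 0.44, TNFRSF10D by 0.67 and FDXR by -0.01. The parts were at 0.32 for arrest, 0.13 for apoptosis, 0.03 for repair, 0.25 for feedback and 0.06 for metabolism. Repair (12 genes, percentile 72.0) and metabolism (42 genes, percentile 96.0, interval -0.03 to 0.12) did not stand apart. Of the 716 genes with a mean response of at most -1, 361 had a smaller response in LIMA1 shRNA cells (50.4%, 46.7% to 54.1%); this share was 44.2% with a size of 1.5-fold and 54.6% with a size of 2.

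The ATF4 list, which was high in untreated LIMA1 shRNA cells, differed the other way. It had a median difference of -0.45 (-0.84 to -0.24), below every random list, with CHAC1 at -3.37, DDIT3 at -1.95, STC2 at -1.36 and TRIB3 at -1.20. This difference, the higher list in untreated LIMA1 shRNA cells and the lower list with nutlin-3a in that line all rest on the 1 untreated LIMA1 shRNA library, so they are not independent results. SESN2 was the only p53 target at or below -1 (-2.15), and PMAIP1 (-0.98), BBC3 (-0.59) and GDF15 (-0.51) were also below 0. G2/M genes were at -0.22 (-0.38 to 0.00), with KIF4A (-1.29) and AURKB (-1.28) lower, and at -0.09 with a pseudocount of 30, as these genes are low with nutlin-3a. NRF2 (-0.10) and sterol genes (-0.08) stood apart on the low side, whereas actin (0.04, and 0.015 without the length and GC trend) and epithelial genes (0.08) did on the high side. S-phase, mesenchymal, YAP/TAZ, interferon-stimulated, secreted-factor, hypoxia, ribosomal, histone, lineage and housekeeping medians were 0.03, 0.07, -0.01, 0.09, -0.01, 0.02, -0.01, -0.13, -0.0017 and -0.04; the ribosomal median was 0.0069 after upper-quartile scaling. Over all genes 162 differed by at least 1 and 104 by at most -1. With means of at least 150 these were 29 and 29, with a pseudocount of 30, 43 and 41, and without the length and GC trend 97 and 62. The last setting also left out genes without a length, and leaving out lnc- models alone gave 116 and 71. Without shared-read genes the counts were 82 and 45. The largest differences, at C9orf69, NUDT4P1, lnc-ACOT1-2, lnc-BAG2-2 and PPP1R9B, were all in shared-read genes.

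Genes of other cell types were near absent. Of 24 markers of fibroblast, endothelial, blood and other cells, ALB among them, 22 were under the level for a measured gene. None of these 22 had a value above 51.8 normalized counts. CD68 and CD14 were measured, at means of 759 and 85.5.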

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

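The tests of the ATF4 genes, of shared reads and of the larger response were chosen only after the result was seen. The test of counting error was set before its result, and was limited afterwards to genes in the range that was checked for whole fragments. That limit turned its outcome. Before it, the highest simulation lay narrowly under the bound set against counting error, and after it narrowly above.

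C9orf69 had responses of opposite sign in the 2 lines, 7.60 in control shRNA (counting interval 6.22 to 11.13) and -6.59 in LIMA1 shRNA cells (-12.93 to -5.13), a difference of -14.19 that was not tested, as each group has 1 library. Its values were 1.63 and 510 normalized counts in untreated and nutlin-3a control cells, and 210 and 1.20 in the LIMA1 shRNA cells; the low values stand for about 2 and 1 fragments, so these sizes are imprecise. The noncoding model named after it, lnc-C9orf69-1, had 654, 329, 491 and 997 in the same order. The sums of both models were 656, 839, 702 and 998, so they were higher with nutlin-3a in both lines. The opposite signs are thus seen only when the models are counted apart, and they may come from how reads were split between them. C9orf69 is a shared-read gene, and its counting intervals do not cover that split. More widely, of the 262 genes with response differences of at least 1 whose values could be checked, 139 (53.1%, 46.8% to 59.2%) were shared-read genes, above the highest of the expression-matched draws (36.3%; median 26.0%), so reads moved between gene models may account for part of these differences. Among the genes so checked that had no shared reads, counting error alone gave at most 62 such differences in 100 simulations (median 44) against 123 observed, so it could account for a large part of them.

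The higher ATF4 and unfolded protein response genes in untreated LIMA1 shRNA cells (median 0.49) were weighed against technical causes. Removing the trend with transcript length and GC content left a median of 0.55 (0.18 to 0.89), which argues against that trend as the whole cause. Library scaling moves all genes alike, and the range of 95% of expression-matched random lists reached up to 0.12, below the list's interval (0.17 to 0.89). As scaling moves the random lists as much as this list, the gap between them would be there under any scaling. The comparison is thus no test of scaling, and it cannot show where 0 lies. Under every alternative, library scalings among them, the list's median was between 0.44 and 0.55. With nutlin-3a the list's median was 0.010 (-0.07 to 0.21), but STC2, PHGDH and CTH differed in the same direction in both states. With 1 library per group, an effect of the LIMA1 shRNA that is the same in both states, one in untreated cells alone and the state of 1 culture at harvest cannot be told apart.

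The larger response of the 788 induced genes in LIMA1 shRNA cells was weighed in the same way; their median LIMA1 shRNA difference was -0.092 untreated and 0.12 with nutlin-3a. With the length and GC trend removed, which kept only genes with a length, 26.6% (23.2% to 30.2%) of 636 genes had a smaller response. Before, 26.5% of the 788 had, which argues against that trend. Random sets of as many expression-matched genes had a median response difference of at most 0.057, against 0.22 (0.17 to 0.25) for the induced genes. Library scaling moves such sets as much as the induced genes, so this gap is no test of it. The sets cannot test where 0 lies, on which the share of smaller responses depends. A stronger nutlin-3a exposure of 1 culture stays open: of the repressed genes 50.4% had a smaller response (44.2% with a size of 1.5-fold, 54.6% with a size of 2), but repression has a floor, and with 1 culture per group this cannot be told apart from an effect of the LIMA1 shRNA.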

How the results depend on the processing

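The settings with a mean of at least 1, no shared-read genes, no lnc- models, a pseudocount of 30 and removal of the length and GC trend were chosen after seeing the data. No library could be left out of a group. No paired or blocked fit was run; pairing the libraries by line or by treatment would take the response difference as its error. Medians that did not stand apart changed sign in some settings, those of the histone, housekeeping and p53 target lists below among them. Of the list medians 1296 of the values under the alternatives lay within the main interval and 24 outside it. Of the 54 list medians that stood apart, 53 kept their sign in every alternative; the exception was the histone list with nutlin-3a, at 0 without a filter. Counts of genes moved most, since they depend on the filter and the size by construction, and low genes carry large counting error. Below, counts are given as higher and lower, for nutlin-3a in control and in LIMA1 shRNA cells, LIMA1 shRNA in untreated and in nutlin-3a cells, and the response difference. Which direction held more genes turned in some settings. For nutlin-3a in control cells, higher genes outnumbered lower ones with no filter, a mean of at least 1, a size of 1.5-fold and upper-quartile scaling (788 and 662). In LIMA1 shRNA cells lower genes did so with a mean of at least 150 and a size of 2. For LIMA1 shRNA with nutlin-3a, higher genes did so with no filter. With no filter, 1 fragment against 0 is called only when it lies in the nutlin-3a LIMA1 shRNA library. This adds higher genes to each contrast that uses that library, and how many was not counted.

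With no filter the counts were 2743 and 1802, 4268 and 1836, 1223 and 1759, 2448 and 1688, and 2931 and 1998; 1548 genes were higher with nutlin-3a in both lines, and 337 higher and 507 lower with LIMA1 shRNA in both states. The share of induced genes with a smaller response was 36.6%, and the histone medians were -0.95 for nutlin-3a in control cells, 0 for LIMA1 shRNA with nutlin-3a and 0.48 for the response difference. With a mean of at least 1 the counts were 2402 and 1528, 2917 and 1591, 988 and 1459, 1235 and 1326, and 1683 and 1371; 1468 were higher in both for nutlin-3a, 294 higher and 476 lower for LIMA1 shRNA, the share was 37.9% and the histone medians for nutlin-3a were -0.11 and -0.34. With a mean of at least 150, 364 and 482 genes were higher and 518 and 573 lower with nutlin-3a, with 333 higher in both; for LIMA1 shRNA the counts were 42 and 68, then 59 and 78, with 22 and 35 in both; the response difference gave 29 and 29, and the share was 22.2%.

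With a size of 1.5-fold the counts were 1696 and 1626, 1991 and 1861, 442 and 769, 557 and 679, and 476 and 374; in both, 1390 and 1322 for nutlin-3a and 222 and 397 for LIMA1 shRNA. The share of repressed genes with a smaller response was 44.2%. With a log2 size of 2 the counts were 195 and 314, 246 and 302, 27 and 38, 28 and 39, and 37 and 31. In both, they were 161 and 265 for nutlin-3a and 7 and 15 for LIMA1 shRNA, and the share of repressed genes was 54.6%.

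With a pseudocount of 30 the counts for LIMA1 shRNA were 57 and 98 untreated and 82 and 99 with nutlin-3a, 26 and 54 in both, and 43 and 41 for the response difference; the G2/M medians for nutlin-3a were -3.99 and -4.14, the S-phase median in control cells -2.88 and the histone median there 0.25. Without shared-read genes, 106 were higher with LIMA1 shRNA in nutlin-3a cells and the response difference gave 82 and 45. With the length and GC trend removed, which also left out genes without a length, the response difference gave 97 and 62. Leaving out lnc- models alone gave 116 and 71. With the trend removed, ribosomal protein medians were -0.055 for LIMA1 shRNA untreated, -0.057 with nutlin-3a and -0.037 for the response difference. The histone median for LIMA1 shRNA with nutlin-3a was then -0.45.

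With upper-quartile scaling, LIMA1 shRNA in untreated cells had medians of 0.056 for S-phase, 0.11 for sterol, -0.16 for ribosomal protein, -0.021 for housekeeping genes and -0.00056 for the p53 targets; ribosomal protein genes had 0.22 and 0.21 for nutlin-3a and 0.0069 for the response difference. With equal-total scaling, ribosomal protein medians for LIMA1 shRNA were -0.15 untreated and -0.17 with nutlin-3a, and the housekeeping median untreated was -0.013. Each scaling divides a library by 1 factor, so it shifts all genes of a contrast by nearly the same amount. These medians moved with that shift. The upper-quartile factors of the untreated libraries were 1.004 with control shRNA and 1.044 with LIMA1 shRNA. Of the genes tracked, MDM2 was at 4.27 for nutlin-3a in LIMA1 shRNA cells with upper-quartile scaling, and for LIMA1 shRNA with nutlin-3a, at 0.30 as reported, it was at 0.26 and 0.25 with upper-quartile and equal-total scaling. CDKN1A, at 0.50 there, was at 0.46 and 0.45. With the length and GC trend removed these values were 4.11, 0.14 and 0.58, and with a pseudocount of 30 LIMA1 in untreated cells was at -2.18.

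Other medians that stood apart stayed within their intervals but moved by over 1.5-fold. With a pseudocount of 30, LIMA1 shRNA with nutlin-3a had medians of -0.18 for G2/M, 0.14 for S-phase and 0.24 for mesenchymal genes, and the G2/M response difference was -0.09. With the length and GC trend removed, untreated LIMA1 shRNA cells had -0.0077 for G2/M, 0.28 for sterol and -0.32 for histone genes, the actin response difference was 0.015 and the YAP/TAZ median for nutlin-3a in LIMA1 shRNA cells 0.17. The G2/M median in untreated cells was -0.09 with both of the scalings named above.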

Other observations

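The gene groups below were chosen after the data were seen, from 196 groups of genes that share a symbol stem and have at least 8 measured members, and no test was made. Genes of the nuclear pore, the NUP group of 20 genes, had a median mean response to nutlin-3a of -0.86, with 7 lower by at least 1 and 0 higher, and the HAUS group of 8 spindle genes had -1.19, with 6 lower and 0 higher. The COL group of 20 genes, all collagen genes except COL4A3BP, was at 0.54, with 6 higher and 1 lower. The nutlin-3a signs of these 3 groups were kept under every scaling, but the scalings shift medians too little to turn them. With upper-quartile scaling the NUP median was -0.79.

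The nuclear noncoding RNA NEAT1 was at 2715 normalized counts in untreated control cells, 4730 in untreated LIMA1 shRNA cells, 8441 in nutlin-3a control cells and 15332 in nutlin-3a LIMA1 shRNA cells. MALAT1 was at 217, 274, 318 and 954 in the same order.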
